A study of Ovis aries with 30 samples.

How the data were processed

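Gene expression in whole blood of 15 female sheep was measured on 30 single-colour microarrays. Of these animals, 10 received 28 mg of iodide per animal per day for 40 days and 5 served as controls. The sample names give each animal 1 array at day 0 and 1 at day 40, within its arm. That makes 4 groups of 10, 10, 5 and 5 arrays. The times 0 and 40 in the names were read as days of the 40-day trial; the labels call the supplemented arm's time 0 samples unsupplemented, but the series text mentions blood collection only after treatment.

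Per the labels' protocols, RNA from blood stabilised in PAXgene tubes was amplified and labelled with Cy3 by an Agilent single-colour procedure. The values the authors deposited are linear Cy3 intensity values per numbered feature, in 1 table of 45220 features by 30 arrays. The scanner software, background correction, normalization method and the rule that leaves an entry without a value are not given in the sources used here. The sorted values of the arrays of an arm nearly coincided: the intensity at rank 10000 spanned 1.34% across the 20 supplemented arrays and 0.631% across the 10 control arrays. Its median was 550 in the supplemented arm and 587 in the control arm. The deposited intensities had therefore been brought to a common distribution separately in each arm. The 2 changes over time each lie within an arm and its distribution. The comparisons of supplemented with control animals on 1 day set levels across the separate distributions, so their values with 1 quantile normalization of all 30 arrays, over the features tested, are given beside them.

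Feature numbers are not paired with genes in the files used here, and the sheep gene table used for names holds nothing to match them. No feature could be named by gene. The gene lists fixed in advance were not tested, and the alternatives on several probes of a gene were not run. The rule fixed for named genes, the 10 largest rises and 10 largest falls with a gene symbol, could not be met. In its place, only the feature with the largest rise and the feature with the largest fall past the threshold are given by number, for each change over time.

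Intensities were converted to log2 without further normalization or offset. The 22969 features with a value on all 30 arrays were tested. Features that lost their value on any array are outside these tests, so a feature that fell out of range by day 40 was not tested. The model was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over the 4 groups, which share 1 estimate of the spread. Its 5 contrasts were the change from day 0 to day 40 in supplemented animals, the same change in control animals, the difference of these changes, and supplemented minus control animals at day 40 and at day 0. Benjamini-Hochberg adjustment was applied within each contrast, with a threshold of 0.05 on the adjusted p. Figures were drawn with matplotlib 3.10.9.

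The model fixed before the data were examined had no term for the animal, and a model with the animal as a block was fixed as its alternative. Whether the numbers in the sample names pair the arrays was checked before the calls of the models were compared. After the group means were removed, the arrays with the same number correlated at r from 0.31 to 0.65 in the 10 supplemented pairs and from 0.42 to 0.64 in the 5 control pairs. The highest r between a day 0 and a day 40 array of an arm with different numbers was 0.19 and 0.04. Among the arrays of the other day in its arm, every array correlated best with that of its own number. Arrays of the same day were not compared here. The numbers thus pair the arrays by animal, and each count of the animal-block model is given beside the count of the model without it. The block was also fitted as a random effect, with a consensus correlation of 0.508 between the arrays of an animal. No arrays were duplicates: the closest arrays, from supplemented animal 5, differed by a median of 0.13 on the log2 scale.

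The alternatives fixed before the data were examined were the block, the groups in the model, quantile normalization, median centring and a 75th percentile shift of all arrays, dropping the dimmest 33.3% of features, array weights, a trended and robust variance prior, a fold of at least 1.5, unadjusted p, and leaving out each array or animal in turn. Chosen after seeing the data were all alternatives run under the block model, a test of the 36784 features with at least 3 values per group, leaving out supplemented animals 1 and 2, fitting each arm's animals alone with the block, and a term for, or the removal of, the day 40 arrays with the fewest values. Single values per animal were compared with two-sided exact tests, by sign flips within an arm or by permuting animals between arms over all 3003 splits. For changes along features chosen in other supplemented animals, the choice was not repeated for each flip or permutation. The p of those changes serve only as a guide. The number of arrays limits the precision.

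The models were tested on simulated data with 22969 features, 200 of them changed. For the change in supplemented animals, the model without the block found 64% of features changed by 0.5 and 92% of those changed by 1 on the log2 scale, and the block model found 79% and 98%. For the difference of changes these shares were 20% and 66% without the block, and 46% and 84% with it. Of the unchanged features, 1.37% to 1.52% had an unadjusted p under 0.05 without the block over the 3 contrasts involving time. With the block 5.01% to 5.39% did, so the model without it is conservative for these contrasts. Noise was drawn independently for each feature, so the simulation lacks any structure that features share between arrays.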

Results

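Whole-blood transcripts were profiled in 15 female sheep aged 3 to 4 years. The treatment was dietary iodide, the form of iodine that the thyroid takes up to make its hormones. The sample names give arrays at times 0 and 40, read here as day 0 and day 40, for 10 supplemented animals and 5 control animals. The labels call the supplemented arm's time 0 samples unsupplemented, while the series text mentions blood collection only at the end of treatment, so the timing of the time 0 samples rests on the sample labels. Each array reported up to 45220 features, which are given by number because the files used here do not pair them with genes. A value was present on all 30 arrays for 22969 features (50.8%), and on no array for 1193 features (2.64%).

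Fewer features had a value at day 40 than at day 0. In supplemented animals the number was 41952 ± 656 (SD, n = 10) at day 0 and 36116 ± 1955 (n = 10) at day 40. In control animals it was 40371 ± 1354 (SD, n = 5) at day 0 and 37170 ± 1969 (n = 5) at day 40. The change was -5836 ± 2459 features in supplemented animals, lower in 10 of 10 (exact sign-flip p = 0.00195, the smallest that 10 animals allow). It was -3201 ± 1561 in control animals, lower in 5 of 5 (exact sign-flip p = 0.0625, the smallest that 5 animals allow). The missing values were concentrated among dim features. For features with a mean log2 intensity of up to 3, 8.85% of entries had no value at day 0 and 43.1% at day 40 in supplemented animals, against 17.7% and 36.8% in control animals. Above a mean of 9, the share was below 1% in all 4 groups, with a highest value of 0.727%. The 4 day 40 arrays with the fewest values, from supplemented animals 7, 8 and 9 and control animal 1, held 33347 to 33861 values, while the next day 40 array held 35789.

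**Figure D1:**
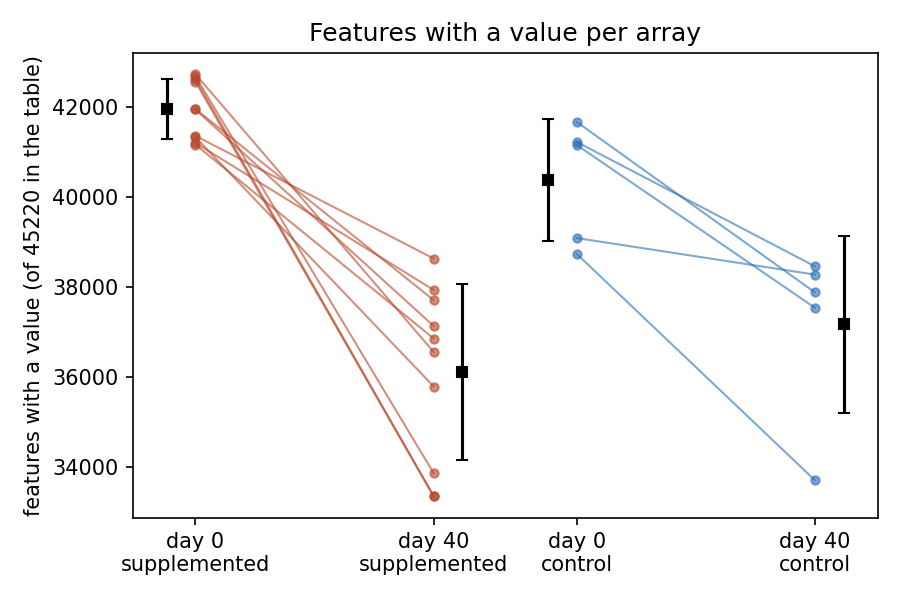
Number of features with a value on each array (vertical axis, which does not start at 0) by day and arm; lines join the arrays of an animal, and squares with bars are the mean ± SD of a group (n = 10 supplemented, n = 5 control). All 15 lines fall from day 0 to day 40, and 4 arrays at day 40 lie at or below 33861.

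The change in supplemented animals over the 40 days was tested on the 22969 features with a value on every array. In the model without an animal term, 646 features changed, of which 406 rose and 240 fell. The median log2 change was 0.39 among those that rose and -0.43 among those that fell, and 23 rose and 6 fell by at least 2-fold. With the animal as a block, 3278 features changed, of which 1808 rose (median 0.27) and 1470 fell (median -0.24); after 1 quantile normalization of all arrays the block model gave 1628 higher and 1639 lower. Of the 646 features, 638 (98.8%) were among the 3278, each in the same direction. In 1283 of the 3278 features (39.1%) all 10 animals moved the same way, but the 3278 were chosen by their change in these same animals. Over all tested features this held for 6.45%, and equal odds of either direction would give 0.195%. Changes were found at every level of intensity: of 3 classes of equal size by mean intensity, 15.1% of the dimmest, 15.7% of the middle and 12% of the brightest features changed in the block model.

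The largest rise in either model was that of feature 25973, by 1.83 on the log2 scale (SE 0.48, adjusted p = 0.036), from 4.63 ± 1.64 to 6.46 ± 0.55 (SD, n = 10), higher in 10 of 10 animals. At day 0 this feature lay below a log2 intensity of 2 in supplemented animals 1 and 2, and without these animals its log2 change was 1.21 (adjusted p = 0.0881, against a range of 0.00128 to 0.0881 over the alternatives). The largest fall in either model was that of feature 15811, with a log2 change of -1.39 (SE 0.25, adjusted p = 0.00416), from 4.43 ± 0.43 to 3.04 ± 0.31 (SD, n = 10), lower in 10 of 10 animals. In control animals the log2 change of feature 25973 was 1.12 (adjusted p = 0.663) and that of feature 15811 was -0.86 (adjusted p = 0.429). Neither was past the threshold in this model. With the block, feature 15811 also fell in control animals (adjusted p = 0.0489). The difference of the 2 changes did not pass for either feature (adjusted p = 0.999 for both). With the block the adjusted p of this difference was 0.695 for feature 25973 and 0.444 for feature 15811. The count was 238 in place of 646 without supplemented animal 2, and 131 (68 higher, 63 lower) without animals 1 and 2; with the block it was 1809 without both. A term for the 4 day 40 arrays with the fewest values gave 1198 features, and 5181 with the block; without the animals of these arrays the counts were 717 and 2998.

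The same interval was compared in the control animals, the arm without the iodide supplement. In the model without an animal term 21 features changed, 12 up and 9 down; with the block 750 changed, 390 up (median 0.34) and 360 down (median -0.51). All 21 were among the 750. All 5 animals moved the same way in 711 of the 750 (94.8%), again features chosen by their change in these same animals. Over all tested features this held for 16.1%, against 6.25% for equal odds. In the model without an animal term, the largest rise was that of feature 29306, by 1.64 (SE 0.30, adjusted p = 0.0206), from 2.22 ± 0.66 to 3.86 ± 0.20 (SD, n = 5), higher in 5 of 5 animals. The largest fall in that model was that of feature 20168, with a log2 change of -1.28 (SE 0.22, adjusted p = 0.0108), from 6.79 ± 0.21 to 5.50 ± 0.39 (SD, n = 5), lower in 5 of 5 animals. In the block model, the largest rise and fall past the threshold were 1.89 and -2.26. At day 0 feature 29306 lay below a log2 intensity of 2 in control animals 1 and 5. Without either of these arrays its log2 change was 1.51 (adjusted p = 0.0574) and 1.47 (adjusted p = 0.0531), and it also missed the threshold without the day 0 array of control animal 4 or the day 40 array of control animal 2 or 4. Both features also passed in supplemented animals, with log2 changes of 0.81 (adjusted p = 0.0335) for feature 29306 and -0.86 (adjusted p = 0.00369) for feature 20168. Feature 29306 also lay below 2 at day 0 in supplemented animals 1 and 2, at 1.83 in both. In these animals it rose to 3.75 and 4.17, while it fell in supplemented animals 5 and 9. Its median log2 change in the supplemented arm was 0.65. Whether it passes there without supplemented animals 1 and 2 was not examined. After 1 quantile normalization of all arrays the rise of feature 29306 in control animals was 1.24 (adjusted p = 0.0578, range over the alternatives 0.000603 to 0.21). The control calls rest on the spread shared with the supplemented arrays: limma on the control arrays alone called 0 features, without or with the block, with 1718 and 3670 at an unadjusted p under 0.05. Without control animal 4, the counts were 3 without the block and 49 (17 higher, 32 lower) with it. The split of the block calls also turned with a fold of at least 1.5 (61 higher, 137 lower).

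**Figure D2:**
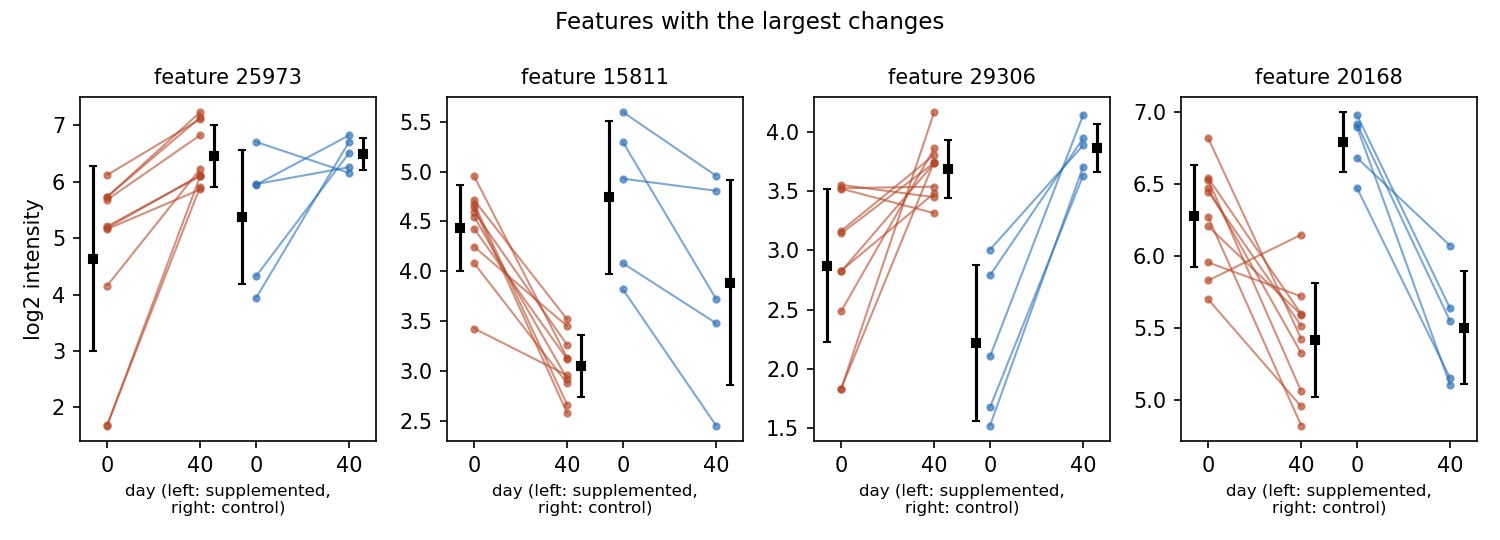
Log2 intensity (vertical axes, on separate scales that do not start at 0) of features 25973, 15811, 29306 and 20168 at day 0 and day 40; lines join the arrays of an animal, supplemented on the left and control on the right of each panel, and squares with bars are mean ± SD (n = 10 and n = 5). Feature 25973 rose in 10 of 10 supplemented and 4 of 5 control animals, and feature 15811 fell in 10 of 10 and 5 of 5. Feature 29306 rose in 8 of 10 supplemented and 5 of 5 control animals, and feature 20168 fell in 9 of 10 and 5 of 5.

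Features that changed in supplemented animals mostly moved the same way in control animals. In the block model, 1531 of the 1808 features that rose (84.7%) had a positive change in control animals, with a median of 0.18 against 0.27 in supplemented animals. Of the 1470 that fell, 1161 (79.0%) had a negative change in control animals, with a median of -0.10 against -0.24. Features that rose in both arms numbered 194, where independent lists of these sizes would share 30.7, and 107 fell in both, where independent lists would share 23.0. Changes in opposite directions past the threshold were found for 16 features that rose and 1 that fell in supplemented animals. Across all 22969 features the changes of the 2 arms correlated at r = 0.354 (Spearman 0.364); features are not independent replicates, and 10 of the 32 exchanges of day within control animals gave a correlation as large in size (exact p = 0.312).

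**Figure D3:**
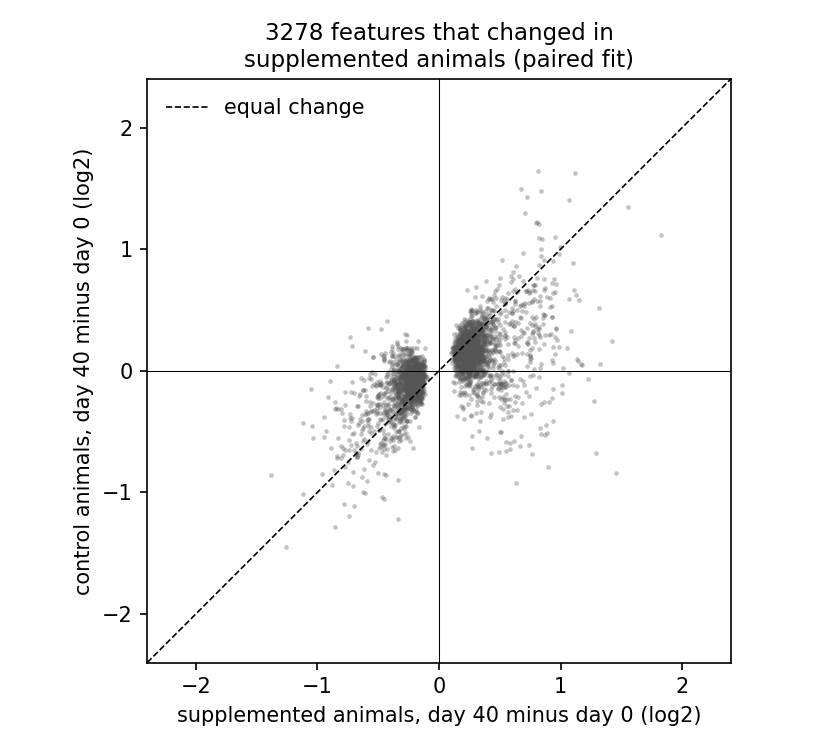
Mean log2 change from day 0 to day 40 in supplemented animals (horizontal axis, n = 10) and control animals (vertical axis, n = 5) for each of the 3278 features that changed in supplemented animals in the block model; the dashed line marks equal change. The gap around 0 on the horizontal axis comes from the choice of features, and 1531 of the 1808 points on the right lie above 0 on the vertical axis.

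Whether supplemented and control animals changed differently, the direct question of the design, was tested as the difference of the 2 changes. In the model without an animal term limma called 0 features (smallest adjusted p = 0.0812), with 1116 at an unadjusted p under 0.05. With the block 45 features differed, and with the animal as a random effect 187. Of the 45, 39 had the more positive change in supplemented animals, with a median change of 0.21 there and -0.59 in control animals, and 37 of these had opposite signs in the 2 arms. The other 6 had the more negative change in supplemented animals (median -0.19 against 0.58). Of the 39, 22 passed in supplemented animals and 33 in control animals. The count of 45 became 7 without control animal 2 or control animal 3 and 87 without supplemented animal 9. A term for the 4 day 40 arrays with the fewest values gave 6 features without the block and 181 with it, and leaving out the animals of these arrays gave 1 and 46.

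**Figure D4:**
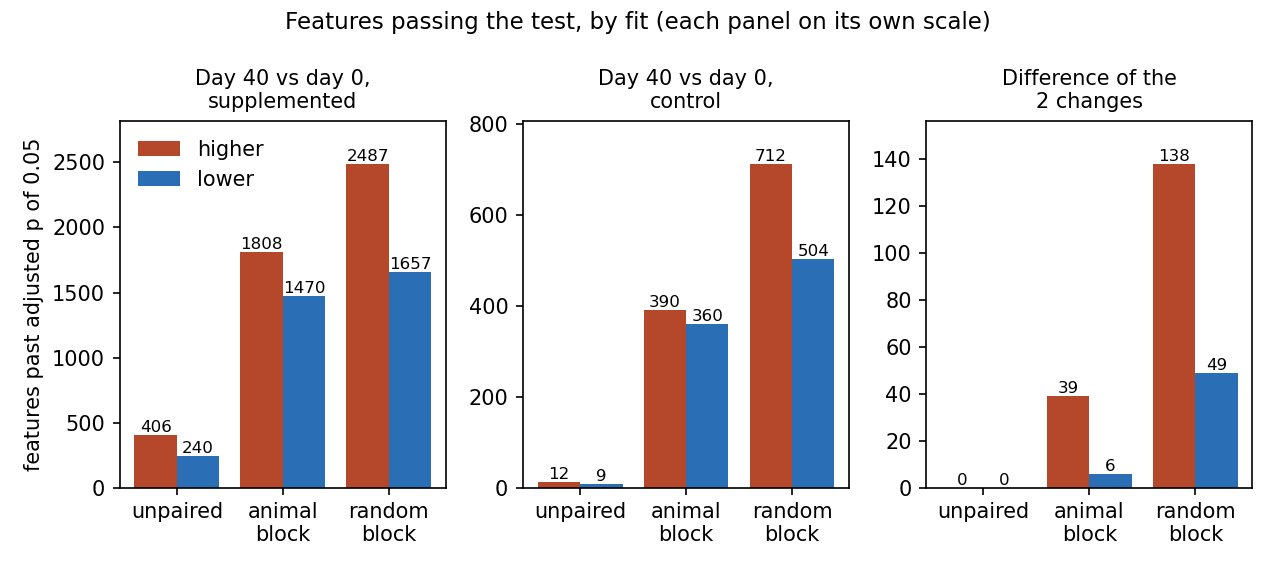
Number of features past an adjusted p of 0.05 (vertical axes, each on its own scale from 0) with a higher or lower value, for the change in supplemented animals, the change in control animals and the difference of the changes; bars compare the model without an animal term, with the animal as a block and with the animal as a random effect. The difference of the changes goes from 0 features to 45 and 187.

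The size of the shared movement was measured per animal. For each supplemented animal, the features that changed in the other 9 (2141 to 3558 features) were taken with their direction, and the animal's own mean signed change along them was computed. It was 0.25 ± 0.07 on the log2 scale (SD, n = 10; 0.14 to 0.36), positive in 10 of 10 (exact sign-flip p = 0.00195, the smallest possible). Along the same features control animals changed by 0.15 ± 0.15 (SD, n = 5; 0.00 to 0.34), positive in 5 of 5 (exact sign-flip p = 0.0625, the smallest possible). The difference of 0.10 did not pass the threshold of 0.05 (exact permutation p = 0.0999). The features were chosen in supplemented animals and were not chosen again for each permutation or sign flip. The supplemented values also depend on each other through the shared animals. The p of these mean signed changes therefore serve only as a guide. It passed without control animal 4 (exact permutation p = 0.015), control animal 5 (exact permutation p = 0.042) or supplemented animal 1 (exact permutation p = 0.049). Without the animals of the 4 day 40 arrays with the fewest values it was 0.19 (exact permutation p = 0.115); supplemented animals 7, 8 and 9 among them had the lowest values of their arm, 0.18, 0.17 and 0.14.

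**Figure D5:**
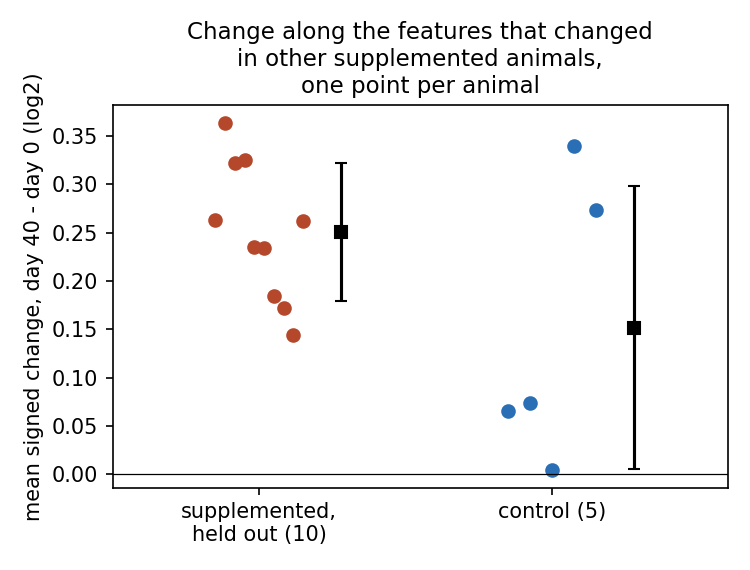
Mean signed log2 change from day 0 to day 40 (vertical axis) along the features that changed in the other supplemented animals, one point per animal; squares with bars are mean ± SD. The 10 supplemented animals lie between 0.14 and 0.36 and the 5 control animals between 0.00 and 0.34, with control animals 4 and 5 inside the supplemented range.

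Supplemented and control animals were also compared within each day. At day 40, 149 features differed, 23 higher and 126 lower in supplemented animals, and at day 0, in samples labelled unsupplemented or control, 121 differed, 22 higher and 99 lower. These levels come from arms normalized separately, and the median of all tested features was shifted by -0.10 on the log2 scale in the supplemented arm. After 1 quantile normalization of all 30 arrays limma called 0 features at either day, with 1658 at day 40 and 2214 at day 0 at an unadjusted p under 0.05. The arrays of day 40 alone, on the deposited values, also gave 0 (3046 at an unadjusted p under 0.05). Median centring gave 67 features at day 40, 57 higher and 10 lower, and 35 at day 0, 27 higher and 8 lower. The features with at least 3 values per group gave 1735 at day 40, 1205 higher and 530 lower, and 2421 at day 0, 1556 higher and 865 lower. The split of the calls between higher and lower thus depended on the scaling and on the features tested. Leaving out a control animal also moved these counts, to between 33 (without animal 2) and 478 (without animal 5) at day 40 and between 43 (without animal 2) and 410 (without animal 4) at day 0; without control animal 3 the day 40 split was 71 higher and 62 lower.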

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

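The tests of supplementation as the whole source of the lost values, of arrays of a time point handled together, of the 4 arrays with the fewest values, of the separate normalization and of dim features as the whole source, and the comparison of the losses between arms, were chosen after the result was seen.

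At day 40, control animal 1 had 33705 features with a value, far from the nearest of the other 4 control animals at 37536. Of 28 groups examined for such a sample, 1 exceeded the limit, and chance gives about 1 in 20. The rule looks for 1 value apart and can miss 2 that lie apart together. At day 0 the 5th percentile of log2 intensity over the tested features was 3.617 and 3.466 in supplemented animals 1 and 2. In the other supplemented animals it was 3.879 to 3.939, and the rule did not flag this group.

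The loss of values differed between the arms: the mean change in features with a value, supplemented minus control animals, was -2635 (exact permutation p = 0.0473). The p lay between 0.027 and 0.147 when each animal was left out in turn, and above 0.05 without supplemented animals 1, 2, 7, 8, 9 or 10 or control animals 2, 3, 4 or 5. With the animals of the 4 day 40 arrays with the fewest values left out, the difference was -1693 (exact permutation p = 0.0606). With all animals, the supplemented arm held more values than the control arm at day 0 (mean 41952 against 40371). At day 40 it held fewer (36116 against 37170). The larger loss of the supplemented arm thus partly reflects its higher day 0 counts.

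Values were also lost in 5 of 5 control animals, with a mean control loss 0.549 times the supplemented loss (SE 0.14), which argues against supplementation as the whole source. A handling difference between the arrays of day 0 and day 40 remains open, since 15 of 15 animals lost values and every animal's later sample is a day 40 sample; time and handling cannot be told apart here. For part of the loss, a candidate explanation is an array batch that holds the day 40 arrays of supplemented animals 7, 8 and 9 and control animal 1. In these animals 75 features changed differently from the rest, and 1 of 100 sets of 3 supplemented and 1 control animals, the real one, gave as many (highest other 5). The real set was picked for its low counts in these same data, while the other sets were drawn at random. The tested features have a value on every array. The comparison therefore cannot show that a batch caused the lost values. At day 0 the same animals differed from the others in 0 features (highest other set 11), and at day 40 in 13, which 3 of 100 sets reached (highest other 532). Their numbers of values at day 0 lay near an end of the range of their arm. Supplemented animals 7, 8 and 9 then held 42558 to 42679 values, near animal 10 (42726), against at most 41953 in animals 1 to 6. Control animal 1 held 38733, the fewest at day 0, near control animal 2 (39086). The larger losses of supplemented animals 7, 8 and 9 thus partly reflect higher day 0 counts. The labels give no batch, and no biological explanation was tested for these 4 animals.

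The difference of the 2 changes held 45 features in the block model. Of 100 splits of the 15 animals into 10 and 5, drawn from 3003, 2 gave as many, a share under 0.05. The highest other split gave 951, so a split that crosses the arms can call more features than the arms. The real count also fell to 7 without control animal 2 or 3. These splits therefore do not establish the arms as the source of the 45. That split put supplemented animals 7, 8 and 9 with control animals 1 and 3, so it points to a structure of the samples that overlaps the arrays with the fewest values. A term for those 4 arrays gave 181 features, while leaving out their animals gave 46. In the model without the block the real count was 0 (highest other 1), which 100 of 100 splits must reach, so that comparison says nothing about chance.

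The change of supplemented animals over 40 days was beyond chance splits: 1 of 100, the real one, gave 646 features or more (highest other 18). No other split drawn parted all 10 animals, so this share excludes only a chance split drawn without regard to the animal. With the block, 1 of 100 exchanges of day within animals, which keep the pairs, gave 3278 (highest other 558). Dim features as the whole source of the block calls are argued against: 1205 and 919 of the 3278 lay in the middle and brightest 33.3% of features. A new fit without the dimmest 33.3% called 2438 features, a count equal to 74.4% of 3278, though not all of them are among the 3278. A partial share stays open because the brightest 33.3% changed at 0.795 times the rate of the dimmest. The share of dim features is larger without the block: 315 of the 646 lay in the dimmest 33.3%, against 1154 of the 3278 with the block. Without the block 1.8% of the brightest and 4.11% of the dimmest changed, and a new fit without the dimmest called 269. A change common to both arms over the same days and supplementation both stay open: control animals moved along the same features by 0.605 times the change of held-out supplemented animals (SE 0.27; 0.418 to 0.752 with each control animal left out), and the arms differed with an exact permutation p of 0.0999. With 5 control animals that spread from near 0 to the supplemented range, the shared change and the supplement cannot be told apart along these features.

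In control animals, 3 of 100 splits of the 10 arrays gave 21 features or more, which excludes only a chance split drawn without regard to the animal. The highest other, with 134, parted the arrays of only 1 animal. The 13 other splits drawn that parted all 5 animals gave 0, and they are too few for a share under 0.05. With the block, 16 exchanges of day within animals are too few as well (real count 750, highest other 23).

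Between the arms on a single day, 2 of 100 splits gave 149 features or more at day 40 (highest other 225) and 1 of 100 gave 121 at day 0 (highest other 13). The shares are under 0.05 for the deposited values. The other splits mix arrays of the 2 separate distributions, while the real split carries the whole offset between them. These shares therefore cannot decide whether the animals differed beyond chance. The separate normalization of the arms is a candidate source of these calls, since 0 features were called at day 40 after 1 quantile normalization of all arrays. A supplementation effect at day 40 was not separated from it, and 121 features were called between samples labelled unsupplemented and control at day 0, whose timing rests on the sample labels.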

How the results depend on the processing

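The block itself was fixed beforehand, while all further settings run under it, the settings with at least 3 values per group, with animals left out together, with an arm's animals alone under the block and with the 4 day 40 arrays with the fewest values, and all alternatives of the held-out change and the lost values, were chosen after seeing the data. The order of values below is change in supplemented animals, change in control animals, difference of changes, arms at day 40 and arms at day 0, and the cause of a shift was not tested unless stated. Without the block these counts were 646, 21, 0, 149 and 121; with it, the first 3 were 3278, 750 and 45.

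The replicate block gave 3278, 750 and 45, and as a random effect 4144, 1216, 187 and, at day 0, 74; it removes the differences between animals. Only the groups of a contrast gave 1002, 0, 0 at day 40 and 70 at day 0, with the control arm's animals alone under the block also at 0. Quantile normalization gave 0 and 0 between arms, median centring 67 and 35, and the 75th percentile shift 70 (54 higher, 16 lower) and 33 (24 higher, 9 lower). Quantile normalization also moved the share of higher calls in supplemented animals from 62.8% to 50.4% (347 higher, 341 lower) and in control animals from 57.1% to 45.0% (9 higher, 11 lower), and under the block to 49.8% in supplemented animals (1628 higher, 1639 lower) from 55.2%. Without the dimmest 33.3% of features, which tests fewer features, the counts were 269, 1 and, at day 0, 3, with 21 for the difference under the block. Array weights gave 1107, 1 for the difference, 939 and 70. The trended and robust prior gave 58 at day 0 and 80 for the difference under the block. The added fold of 1.5 gave 173, 13 at day 40 and 51 at day 0, and under the block 326 and 198 (61 higher, 137 lower). Unadjusted p gave 4076, 2126, 1116, 3085 and 3296, and under the block 7401, 4937 and 2903.

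At least 3 values per group gave 157 in control animals, 1 for the difference, 1735 (1205 higher, 530 lower) and 2421 (1556 higher, 865 lower) between arms, and 17 for the difference under the block. Without supplemented animals 1 and 2 the counts were 131 and, at day 40, 77, and under the block 1809 and 1177; the held-out difference became 0.13 (exact permutation p = 0.0396). A term for the 4 day 40 arrays with the fewest values gave 1198, 40, 6 and, at day 0, 276, and under the block 5181, 1704 and 181. Without their animals the counts were 7 in control animals, 1 for the difference, 38 and 34 between arms and 193 (78 higher, 115 lower) in control animals under the block, with 717 in supplemented animals and, under the block, 2998 and a difference of 46 close to the counts with all animals, the held-out difference was 0.194 (exact permutation p = 0.115) and the difference of lost values was -1693 (exact permutation p = 0.0606).

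Leaving out each array or animal in turn gave 238 (without supplemented animal 2) to 784, 3 (without control animal 4) to 72 (17 higher, 55 lower, without control array 3 of day 40), 0 to 4, 33 (without control animal 2) to 478 (without control animal 5) and 43 (without control animal 2) to 410 (without control animal 4). Under the block, leaving out each animal gave 1982 (without supplemented animal 3) to 3870, 49 (17 higher, 32 lower, without control animal 4) to 1102 and 7 (without control animal 2 or 3) to 87 (without supplemented animal 9). With each animal left out, the held-out difference between arms ranged from 0.062 (without control animal 3) to 0.153 (without supplemented animal 8) and passed the threshold without supplemented animal 1, control animal 4 or control animal 5; the exact permutation p ranged from 0.015 to 0.283. The difference of lost values ranged from -3091 to -2037. The changes of features 25973, 15811, 29306 and 20168 kept their direction in every alternative that tested them; all 4 lie among the dimmest 33.3% and were not tested when these were dropped. Feature 15811 stayed past the threshold in each of those that tested it, while 14, 8 and 5 of the 45 single omissions put features 25973, 29306 and 20168 above it. Below a log2 intensity of about 3, where 43.1% of entries lacked a value in supplemented animals at day 40, the signal limits what could be tested.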

Other observations

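Some features differed between animals by far more than they changed over time, and did so on both days. A spread of at least 4 on the log2 scale (16-fold) between animals, together with a correlation above 0.9 between day 0 and day 40, was found for 51 features in the 10 supplemented animals and 42 in the 5 control animals. These limits were set after seeing the data and serve as a filter, not a test. Of these, 13 features were in both lists, where independent lists would share 0.0933. The widest spread between animals was 11.25 in the supplemented arm and 11.06 in the control arm, while the median over all features was 0.62 and 0.49. The 80 features in either list had a median log2 intensity of 6.77 and a median change over the 40 days of 0.16 in size, and 13 of them changed in supplemented animals in the block model.

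Features that had a value on every array at day 0 and on none at day 40 numbered 75 in supplemented animals, with a median log2 intensity of 2.09, and 105 in control animals. The reverse was found for 0 features in supplemented and 12 in control animals. The rule is stricter in the supplemented arm, with 10 arrays per day against 5 in the control arm. These counts therefore cannot be compared between the arms.

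The arrays of supplemented animals 1 and 2 at day 0 stood apart on the third principal component, which held 8.49% of the variance, with scores of 51.7 and 41.0. These animals hold the low day 0 values of feature 25973, and those of feature 29306 in the supplemented arm.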
